A study of Homo sapiens with 18 samples.

How the data were processed

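RNA sequencing was analysed for 18 libraries of human U937 and THP-1 cells, both described in the labels as acute myeloid leukemia lines. Per the labels' protocols, a lentiviral knockdown of S100A9 was made in U937 cells and a lentiviral overexpression of S100A9 in THP-1 cells, each with its own empty vector control. Puromycin at 2 µg/mL was started 48 hours after transduction and kept for at least 24 hours. THP-1 cells with either vector were also treated with Adavivint at 1 µM for 36 hours. Total RNA was isolated with TRIzol. The libraries fell into 6 groups of 3 by their titles.

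The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library and 18670 genes. The deposited counts were whole numbers without normalization, and every column was matched to 1 library by the column name quoted in its label. HISAT2 2.0.4 was named in the submitters' processing notes. The read counter, the genome build, the annotation and the strand setting are not given in the sources used here. Reads of overlapping genes, of antisense genes and of near-identical paralogs can therefore be shared, and values of readthrough genes (annotated loci that join neighbouring genes, such as ATP6V1G2-DDX39B) and of the pair HSPA1A and HSPA1B are uncertain. Symbols were taken from a name table for 18642 of the genes, and 28 genes had no entry. Positions were taken from GENCODE 29 on GRCh38, in which 18482 of the identifiers were found and 18402 were protein-coding. These positions belong to that annotation, since the build of the counting is not known.

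Totals ran from 38.4 to 84.4 M counts (M stands for 1e6). A gene without a count in the 3 libraries of a group was given the floor of 3 counts over the group, between 0.0147 and 0.0242 CPM, and folds against such a group are stated as lower bounds. Where a group had 1 to 3 counts, the ratio carries an exact 95% interval from the counts. Intervals and floors cover counting error alone. Replicates were compared before averaging: the chi-square per degree of freedom of each pair lay between 7.43 and 235, so no pair agreed within sampling noise and each library was counted once. No label says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

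Gene tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filter filterByExpr and Benjamini-Hochberg adjustment. Genes with an adjusted p below 0.05 are said to have changed. The U937 comparison used the 6 U937 libraries and tested 13016 genes. The THP-1 comparisons used 1 fit of all 12 THP-1 libraries over 15403 genes, with contrasts for overexpression, for the drug with each vector, for overexpression under the drug and for the difference between the drug effects (the interaction). Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes within each line. Adjusted p values of single genes in the text are those of edgeR.

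A set of 41 gene lists was tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided, adjusted over the lists of a comparison). In U937 cells 40 lists had enough members. The lists covered Wnt signalling, kinases and splicing factors, S100 genes, myeloid and immune programs, proliferation, apoptosis, drug handling, metabolism, stress responses, histones and markers of other cell types, and S100A9 was removed from each. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

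The named genes were chosen by rule: S100A9, S100A8 and S100A12; in each comparison the 10 higher and 10 lower genes (5 and 5 for the interaction) with the largest log2 fold change among changed genes with at least 5 CPM in the higher group and no overlap between libraries (no overlap condition for the interaction), leaving out clone and locus names; up to 4 members of each list that passed, by smallest p; CLK1, CLK2, CLK3, CLK4, DYRK1A, CTNNB1, AXIN2 and MYC in the drug comparisons; and the 10 genes with the largest opposite changes in each pair of comparisons. Groups, tests, lists and this rule were fixed before the data were examined.

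Calls shared by pairs of comparisons were set against the overlap of independent lists. Where pairs shared libraries, 10 simulations without any effect gave the correlation and covariance due to the shared libraries. Direction was tested with Fisher's exact test (two-sided).

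The gene and list tests were first tested on simulated counts with 200 changed genes. With the U937 layout, edgeR recovered 55 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, with 8 unchanged genes called. With the THP-1 overexpression layout it recovered 92 and 97 of 100, with 5 unchanged genes called. DESeq2 recovered 83 and 97 of 100 with the U937 layout, with 63 unchanged genes called. With the THP-1 layout DESeq2 recovered 93 and 97 of 100, with 26 unchanged genes called. Alternatives were DESeq2 size factors in edgeR, library totals without composition factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the replicate number as a block, the 2 compared groups alone, a size threshold of 2-fold and leaving out each library. Alternatives for U937 without the pair of libraries that stood apart were added after seeing the data. Their effects are given in the closing section.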

Results

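The study profiled gene expression after S100A9 was lowered in U937 cells or raised in THP-1 cells, and after THP-1 cells were treated with Adavivint, with the stated aim of describing the response to each. S100A9 encodes a calcium-binding protein of myeloid cells that pairs with S100A8. U937 and THP-1 are established human monocytic lines. Adavivint (lorecivivint) is a small molecule described as an inhibitor of the kinases CLK2 and DYRK1A and of Wnt signalling. Polyadenylation or other selection of the RNA is not given in the sources used here. The 6 groups of 3 libraries held 41.9 to 49.5 M counts for U937 empty vector, 56.8 to 82.0 M for U937 shS100A9, 49.7 to 61.4 M for THP-1 empty vector, up to 84.4 M for THP-1 overexpression, 41.8 to 45.2 M for empty vector with drug and 38.4 to 45.3 M for overexpression with drug.

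S100A9 followed the labels in every group. In U937 cells it fell from 6.14 ± 1.44 to 0.225 ± 0.170 CPM (SD, n = 3 each), 27.6-fold (log2 fold change -4.79, SE 0.62, adjusted p = 0.0205). In THP-1 cells the overexpression vector raised it from 6.38 ± 2.79 to 28.1 ± 1.57 CPM, 4.36-fold (log2 fold change 2.13, SE 0.20, adjusted p = 3.2e-05). Adavivint raised S100A9 with both vectors, to 13.9 ± 1.13 CPM in empty vector cells (2.16-fold, adjusted p = 0.000174) and to 107 ± 5.15 CPM in overexpressing cells (3.80-fold, adjusted p = 2.48e-07). The difference between these drug effects was 0.81 on the log2 scale (SE 0.28) and did not pass the test (adjusted p = 0.0548). It passed with DESeq2 size factors in edgeR (adjusted p = 0.0495), with a filter of 1 CPM in 3 libraries (0.0481) and without empty vector 2 (log2 difference 1.07, adjusted p = 0.00485). S100A9 (ENSG00000163220) lies on chromosome 1 at 153357854 to 153361027 on the plus strand and has 3 exons. The counts do not separate vector transcripts from transcripts of the endogenous gene. The knockdown call rested on few libraries: its adjusted p was 0.0947 without empty vector 1, 0.104 without empty vector 3, 0.136 without shS100A9 1 and 0.0526 without shS100A9 2, while the log2 fold change stayed between -5.54 and -4.30 over the 6 fits that left out 1 library.

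In overexpressing cells S100A8, the partner of S100A9, was lower, at 0.400 ± 0.196 against 0.819 ± 0.252 CPM (log2 fold change -0.99, SE 0.30, adjusted p = 0.0256), a call kept in 3 of the 6 fits that left out 1 library. Adavivint raised S100A8 5.01-fold in empty vector cells (adjusted p = 1.79e-06) and 13.4-fold in overexpressing cells (adjusted p = 1.84e-08). In U937 cells the S100A8 difference did not pass the test (log2 fold change -1.38, SE 0.60, adjusted p = 0.371). S100A12 had between 0 and 15 counts per group and was not tested.

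**Figure D1:**
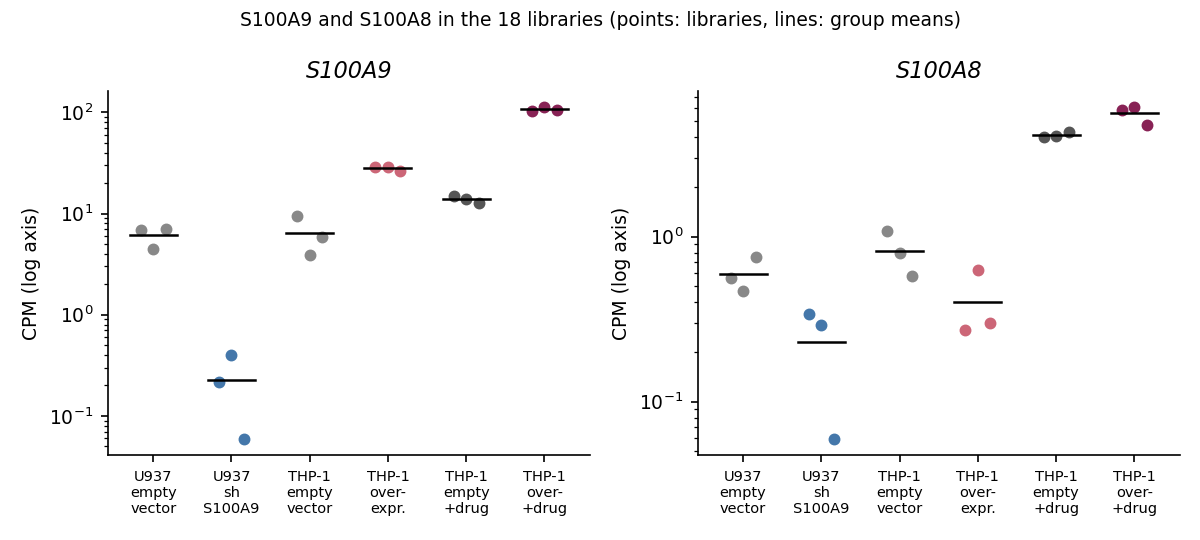
S100A9 (left) and S100A8 (right) in CPM on log axes, with 1 point per library and a line at the mean of each group of 3. S100A9 fell from 6.14 to 0.225 CPM in U937 cells and rose from 6.38 to 28.1 CPM in THP-1 cells, and the 3 overexpression libraries with drug lay near 107 CPM.

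The first comparison asked which genes changed when S100A9 was lowered in U937 cells. In this fit the changes that passed were mostly losses: 201 genes were lower and 30 higher of 13016 tested. The balance depended on the fit. DESeq2 gave 562 lower and 228 higher genes, but on simulated counts of this layout it called 63 unchanged genes, against 8 for edgeR. Leaving out the 2 libraries that stood apart, described below, gave 2308 lower and 1988 higher. Several genes were almost lost. AFDN, which encodes the junction protein afadin, fell from 25.9 ± 1.51 to 0.301 ± 0.0726 CPM (n = 3 each), 85.9-fold. SNRPN, a small ribonucleoprotein gene of an imprinted region, fell 173-fold from 20.1 ± 2.73 CPM, and the surface protein gene CD109 fell 56.3-fold. RAPGEF6, an exchange factor for RAP proteins, fell from 11.6 ± 0.574 to 0.0324 ± 0.0309 CPM. GPR85, an orphan receptor, and SPRED1, a repressor of RAS-MAPK signalling, had 3 counts each in the 3 knockdown libraries. Their ratios of empty vector to knockdown were 557 (95% counting interval 190 to 2707) and 439 (150 to 2131). The protease inhibitor gene SPINT1 fell 11.5-fold, the low-affinity IgE receptor FCER2 9.42-fold and the immune receptor CD180 8.89-fold.

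Gains were smaller among the genes named by rule. IFI44, not among them, rose more: its empty vector level was less than 0.1 of its knockdown level. KYNU, an enzyme of tryptophan breakdown, rose 3.02-fold from 5.46 ± 1.76 to 16.5 ± 1.22 CPM (adjusted p = 0.0338), and the calcium channel gene RYR2 rose 2.74-fold. PPFIA4 rose 2.55-fold, CACHD1 2.49-fold, SHROOM2 2.44-fold, ZNF440 2.34-fold, FMNL2 2.28-fold and the interferon-induced gene OAS2 2.22-fold (adjusted p 0.00737 to 0.0460).

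Cholesterol synthesis genes fell in the knockdown: 6 of 22 measured members were lower and none higher over all genes tested, and 16 were lower when adjusted over the list alone (camera adjusted p = 1.13e-24; adjusted p = 0.792 with an estimated correlation). HMGCS1 fell 3.90-fold from 175 ± 30.3 to 44.9 ± 3.65 CPM (adjusted p = 0.00426), MSMO1 2.94-fold, IDI1 2.69-fold and SC5D 1.91-fold. Among 19 monocyte and macrophage markers, CD68 fell 2.24-fold and FCER1G 1.93-fold, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.000944; adjusted p = 0.792 with an estimated correlation). Glycolysis and hypoxia genes rose as a list, with 3 of 30 higher (4 adjusted over the list alone): ALDOC 2.66-fold, ENO2 2.32-fold and NDRG1 2.02-fold (camera adjusted p = 0.000253; adjusted p = 0.833 with an estimated correlation). Of 28 lysosomal genes NPC1 fell 1.96-fold and GLA 1.86-fold, with 6 lower adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.833 with an estimated correlation). Ribosomal protein genes shifted upward as a list (mean log2 fold change 0.17, camera adjusted p = 9.76e-06) and heat shock genes downward (-0.42, camera adjusted p = 0.0227), without a changed member in edgeR over all genes or adjusted over the list alone. At an unadjusted p below 0.05, 11 of 77 ribosomal protein genes were higher and 2 lower, and 4 of 17 heat shock genes were lower. DESeq2 called 1 ribosomal protein gene higher and 1 lower, and 2 heat shock genes lower. With an estimated correlation both had an adjusted p of 0.833.

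The U937 count depended on single libraries. Empty vector 2 and shS100A9 3 stood apart from their groups, with a chi-square per degree of freedom of 141 and 149 against the other empty vector libraries, which differed by 8.33 from each other, and of 175 and 235 against the other knockdown libraries, which differed by 13.6. Without both, an alternative chosen after seeing the data, 4296 genes passed, and the 231 genes of the 6-library test were all among them with the same direction. With 1 library left out the count was 18 without empty vector 1, 362 without empty vector 2, 20 without empty vector 3, 21 without shS100A9 1 and 21 without shS100A9 2. AFDN, SNRPN, CD109, RAPGEF6, GPR85, SPRED1, FCER2 and HMGCS1 passed in each of the 6 fits, whereas the other genes named for this comparison did not, with an adjusted p of up to 0.226. With the replicate number as a block, 36 of the 40 genes named with a U937 value lost their call. The log2 fold change moved from -8.97 to -11.76 for GPR85 and from -7.43 to -8.04 for SNRPN without shS100A9 3, from -8.54 to -11.53 for SPRED1 and from -5.82 to -6.46 for CD109 without shS100A9 1, and from -8.50 to -9.43 for RAPGEF6 without shS100A9 2. In these fits GPR85 and SPRED1 had no count left in the knockdown libraries. Their values of -11.76 and -11.53 are thus set by the fit and are not measured folds.

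The next comparison asked which genes changed when S100A9 was raised in THP-1 cells. Of 15403 genes tested, 2297 were higher and 2010 lower, but 283 passed with a change of at least 2-fold. ALDH1L2, a mitochondrial folate enzyme, rose 4.39-fold from 10.1 ± 2.95 to 44.4 ± 1.80 CPM (n = 3 each, adjusted p = 1.72e-05), and CHAC1, a glutathione-degrading enzyme, rose 3.08-fold. The interferon-induced chemokine gene CXCL10 rose 4.67-fold (29.6 ± 1.07 against 6.27 ± 6.06 CPM, adjusted p = 0.00325). The keratin gene KRT16 rose 4.58-fold and KRT17 2.89-fold, MYO3B 3.32-fold, RIC3 3.22-fold and LRATD2 2.93-fold. The readthrough locus ATP6V1G2-DDX39B rose 12.1-fold, and ABHD14A-ACY1 fell 5.91-fold; reads of such loci can belong to the genes they join. GZMA, which encodes a granule protease, fell 4.04-fold, the signalling repressor gene SPRY4 2.99-fold and the chemokine gene CCL2 2.95-fold. The chaperone gene HSPA8 fell from 1434 ± 546 to 497 ± 11.7 CPM (2.89-fold, adjusted p = 0.000113), ID1 fell 2.76-fold, ID3 2.67-fold and SDF2L1 2.46-fold.

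The ATF4 amino acid response was the list with the lowest p in this comparison: 29 of 31 members were higher and none lower, also when adjusted over the list alone (camera adjusted p = 1.08e-53; adjusted p = 0.00366 with an estimated correlation). ATF5 rose 2.57-fold, asparagine synthetase (ASNS) 2.41-fold from 46.5 ± 4.03 to 112 ± 3.08 CPM, DDIT3 1.90-fold and MTHFD2 1.59-fold. Cholesterol synthesis genes fell, 18 of 23, as many adjusted over the list alone (camera adjusted p = 6.03e-30; adjusted p = 0.127 with an estimated correlation), with INSIG1 down 2.04-fold, IDI1 1.94-fold, DHCR7 1.72-fold and FDFT1 1.40-fold. Heat shock genes fell, 15 of 17, and 16 adjusted over the list alone (camera adjusted p = 9.34e-21; adjusted p = 0.200 with an estimated correlation). Among them BAG3 fell 1.57-fold, and HSPA1A 2.86-fold and HSPA1B 2.63-fold, a pair of near-identical genes whose reads can be shared. In the unfolded protein response 14 of 20 genes fell and 2 rose, the same counts as adjusted over the list alone (camera adjusted p = 1.73e-07), with MANF down 1.96-fold and PDIA4 1.71-fold. NRF2 antioxidant genes fell in 12 of 19 cases and rose in 3, or 13 and 4 adjusted over the list alone (camera adjusted p = 4.27e-05), with OSGIN1 down 2.59-fold and NQO1 1.61-fold. With an estimated correlation the adjusted p was 0.541 for the unfolded protein response and 0.247 for the NRF2 genes.

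In the NF-kB and inflammatory list 13 of 31 genes were higher and 3 lower (14 and 3 adjusted over the list alone; camera adjusted p = 0.00152), among them BIRC3 2.35-fold, RELB 2.10-fold, NFKB2 1.89-fold and the inhibitor gene NFKBIA 1.58-fold. Of 35 type I interferon genes 9 were higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.00261), with RSAD2 up 1.79-fold, IFIH1 1.73-fold and XAF1 1.65-fold. Of 11 MHC class II genes 5 were higher, also adjusted over the list alone (camera adjusted p = 0.00157), with HLA-DRA up 2.83-fold at 2.07 ± 0.162 CPM and its activator CIITA 1.82-fold. With an estimated correlation the adjusted p was 0.541 for NF-kB, 0.247 for interferon and 0.269 for MHC class II genes. Of 9 epithelial and kidney-line markers, KRT17, KRT14 (2.21-fold) and CLDN7 (2.37-fold) were higher, also adjusted over the list alone (camera adjusted p = 0.0446, and 0.0546 with library totals; adjusted p = 0.541 with an estimated correlation), all at or below 6.22 CPM. Without empty vector 1 CLDN7 had a log2 fold change of 0.90 against 1.24 and did not pass. The lists of erythroid, lymphoid, platelet and stromal markers did not pass (camera adjusted p 0.781 to 0.961).

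Genes of ribosomes and mitochondria changed by smaller amounts. Of 77 cytosolic ribosomal protein genes 38 rose (52 adjusted over the list alone; camera adjusted p = 4.29e-09), with RPL15 up 1.23-fold and RPL4 1.18-fold. Of 38 ribosome biogenesis genes 23 fell (27 adjusted over the list alone; camera adjusted p = 7.37e-09), with NOP16 down 1.62-fold and NOLC1 1.32-fold. Nuclear oxidative phosphorylation genes fell in 30 of 68 cases and rose in 1 (33 and 2 adjusted over the list alone; camera adjusted p = 5.57e-08), and 3 of 13 mitochondrially encoded genes fell, with MT-CYB down 1.60-fold (3 adjusted over the list alone; camera adjusted p = 0.00261). Of 30 lysosomal genes 13 fell and 5 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.0362), with CTSA down 1.72-fold and LAMP1 1.52-fold. Of 30 mitotic genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0309), with CDC20 down 1.37-fold. None of these 6 lists passed with an estimated correlation: the adjusted p was 0.269 for the lysosomal genes, 0.719 for the mitotic genes and 0.541 for the rest. Without overexpression 2 the number of changed genes was 2735. ABHD14A-ACY1 kept its call in 3 and CCL2 in 4 of the 6 fits that left out 1 library, with an adjusted p of up to 0.115 and 0.0532, and their log2 fold changes moved from -2.56 to -0.89 without empty vector 3 (-3.18 without overexpression 3) and from -1.56 to -0.52 without empty vector 1, where that of CXCL10 moved from 2.22 to 3.40.

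**Figure D2:**
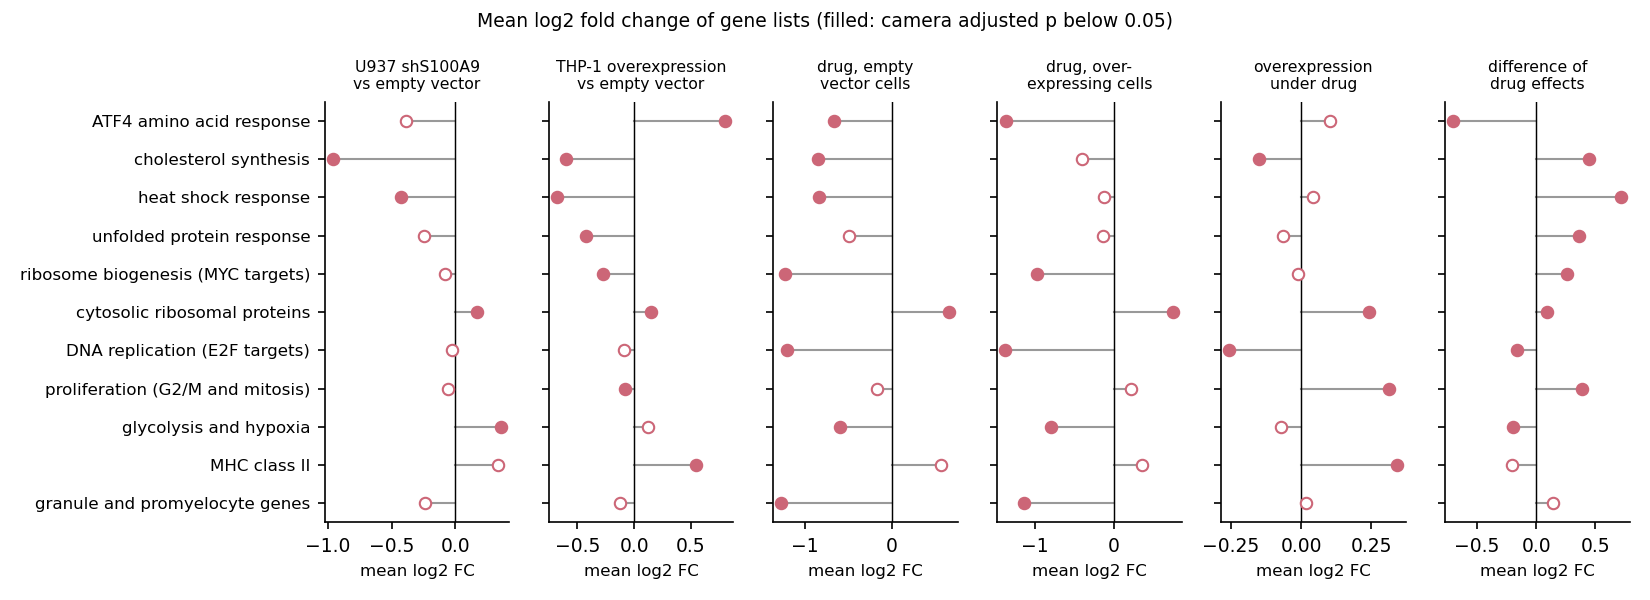
Mean log2 fold change of the members of 11 gene lists in the 6 comparisons, each panel on its own scale, with filled circles where camera gave an adjusted p below 0.05. The ATF4 list lay at 0.80 for overexpression and at -0.70 for the difference of the drug effects, and ribosomal protein genes lay above 0 in every panel.

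Knockdown and overexpression move S100A9 in opposite directions, so genes that follow S100A9 in both lines would change in opposite directions. This was the less frequent outcome: of 12912 genes tested in both, 67 changed in both, 45 in the same direction and 22 in opposite directions, where independent lists would give 34.0 and 36.7. All 22 opposite genes were lower in the knockdown and higher in the overexpression, where independent lists would give 32.3. Of the 45 others 14 were higher and 31 lower in both. The directions were associated, toward the same direction (Fisher's exact test, two-sided, p = 4.15e-05). The opposite genes with the largest changes were GUCY2F, ZNF827, XAF1, FGD2, WARS1, KCNAB1, FAM107B, KDM7A, CEP70 and TPSB2. The tryptophan tRNA synthetase gene WARS1 fell 2.19-fold in U937 (from 230 ± 61.2 to 105 ± 12.8 CPM, adjusted p = 0.0480) and rose 1.61-fold in THP-1 (from 237 ± 14.7 to 382 ± 7.55 CPM, adjusted p = 2.1e-05). The tryptase gene TPSB2 fell 3.17-fold and rose 1.38-fold, and the interferon-induced gene XAF1 fell from 4.39 ± 2.21 to 0.0721 ± 0.0426 CPM and rose 1.65-fold. The log2 fold changes correlated across genes with r = 0.155 and rho = 0.314; genes are not independent replicates. The U937 side carries the limits given above: without the 2 libraries that stood apart 1365 genes changed in the same and 308 in opposite directions. Of the 10 genes named, TPSB2 kept its U937 call in 6 of the 6 fits that left out 1 library, XAF1 in 4, CEP70, FAM107B and KDM7A in 2, WARS1, ZNF827, FGD2 and KCNAB1 in 1 and GUCY2F in 0, with an adjusted p of up to 0.217. The counts in the same and in opposite directions were 2 and 4 without U937 empty vector 1, empty vector 3 or shS100A9 1, 2 and 3 without shS100A9 2, 121 and 24 without empty vector 2, and 24 and 20 without shS100A9 3.

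The drug comparison in empty vector cells asked what Adavivint did to control THP-1 cells. It changed most of the transcriptome: 6814 genes were higher and 6329 lower, and 7309 passed with a change of at least 2-fold. MYC fell 20.7-fold, from 348 ± 21.3 to 16.8 ± 1.72 CPM (n = 3 each, log2 fold change -4.37, SE 0.11, adjusted p = 2.19e-13). The kinase genes of the drug's target family rose: CLK4 2.98-fold, CLK3 2.77-fold, CLK1 2.75-fold and DYRK1A 2.19-fold, while CLK2 stood at 81.3 ± 7.69 against 73.7 ± 5.63 CPM (adjusted p = 0.0797). CLK2 passed as higher with DESeq2 (adjusted p = 0.0268), with DESeq2 size factors in edgeR (0.0305), with a filter of 1 CPM in 3 libraries (0.0446), without empty vector 3 (0.0281) and without empty vector with drug 1 (0.0258), at a log2 fold change of at most 0.20. CTNNB1, which encodes beta-catenin, rose 1.34-fold, and the Wnt target AXIN2 stood at 0.626 ± 0.334 against 0.699 ± 0.255 CPM (adjusted p = 0.723). The Wnt target list did not pass (5 of 18 higher and 8 lower, camera adjusted p = 0.324), nor did Wnt pathway components (19 of 38 higher and 19 lower, camera adjusted p = 0.847) or SR splicing factors (11 of 18 higher and 5 lower, camera adjusted p = 0.729).

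The largest losses in empty vector cells were RGS18, a regulator of G protein signalling, from 78.0 ± 4.83 to 1.12 ± 0.290 CPM (69.6-fold), ID3 (48.1-fold), the tetraspanin gene CD82 (40.0-fold), FYB1 (37.8-fold), the succinate receptor SUCNR1 (37.2-fold) and DHRS9 (34.8-fold), with SPATA12 and FKBP1C down 54.7-fold and 37.6-fold and the readthrough loci RAB4B-EGLN2 and MSH5-SAPCD1 down 52.6-fold and 33.8-fold. The largest gains were genes without a count in the 3 untreated libraries. The iodide transporter gene SLC5A5 reached 29.3 ± 5.20 CPM (at least 1570-fold higher, against a floor of 3 counts over the group), the BMP antagonist gene GREM1 24.5 ± 6.45 CPM (at least 1314-fold), SLC17A8 12.3 ± 2.38 CPM (at least 659-fold), PRLHR 12.2 ± 1.61 CPM (at least 655-fold), TFCP2L1 11.9 ± 2.69 CPM (at least 636-fold), FBLN5 11.4 ± 1.39 CPM (at least 613-fold) and CYP7A1, the rate-limiting enzyme of bile acid synthesis, 9.82 ± 0.910 CPM (at least 527-fold). The readthrough locus ZFP91-CNTF, SLC36A2 and LDHAL6B were also at 0 without drug and rose at least 815-fold, 542-fold and 526-fold. Of these genes SLC5A5, SLC17A8 and FBLN5 lie within 20 kb downstream of an expressed gene on the same strand. LDHAL6B overlaps an expressed gene on the other strand, whose reads it can share since the strand setting is not known. The log2 fold change of RAB4B-EGLN2 moved from -5.72 to -4.38 without empty vector 1.

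Among gene lists, replication-dependent histone genes rose in all 14 measured members, also adjusted over the list alone (camera adjusted p = 3.58e-06), with H2BC21 up 26.6-fold, H2BC5 20.4-fold, H2BC12 16.5-fold and H2AC18 12.7-fold (adjusted p = 0.259 with an estimated correlation). Cytosolic ribosomal protein genes rose in 75 of 77 cases (camera adjusted p = 1.09e-07), with RPL22 up 2.24-fold and RPL13A 2.05-fold, while ribosome biogenesis genes fell in 36 of 38 (camera adjusted p = 1.91e-07), with MYBBP1A down 6.46-fold and POLR1E 4.30-fold (adjusted p = 0.644 with an estimated correlation for both lists). DNA replication genes fell in 32 of 37 cases and rose in 4 (camera adjusted p = 1.09e-07), with CDC45 down 7.39-fold and MCM6 5.74-fold (adjusted p = 0.644 with an estimated correlation). Granule genes fell in 9 of 11 cases (camera adjusted p = 0.00141), with PRTN3, the proteinase 3 gene, down 8.98-fold, MS4A3 6.18-fold and RNASE2 4.60-fold (adjusted p = 0.259 with an estimated correlation). Lysosomal genes rose in 21 of 30 cases and fell in 9 (camera adjusted p = 0.0301), with GPNMB up 3.15-fold and MAP1LC3B 2.73-fold (adjusted p = 0.461 with an estimated correlation). The CLK, DYRK and HIPK kinase list rose in 8 of 12 cases and fell in 2 (camera adjusted p = 0.0301), with DYRK4 up 4.09-fold and HIPK3 2.04-fold (adjusted p = 0.644 with an estimated correlation).

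Several metabolic and stress lists fell in empty vector cells. Cholesterol synthesis genes fell in 19 of 23 cases and rose in 2 (camera adjusted p = 0.00349; MVD 6.12-fold, FDPS 4.92-fold), and glycolysis and hypoxia genes fell in 16 of 30 and rose in 6 (camera adjusted p = 0.0135; TPI1 6.02-fold, PFKL 5.03-fold, PGK1 4.22-fold). ATF4 genes fell in 20 of 31 cases and rose in 8 (camera adjusted p = 0.00776; PSAT1 8.93-fold, CBS 8.19-fold). Oxidative phosphorylation genes fell in 42 of 68 and rose in 15 (camera adjusted p = 0.0142; ATP5MC1 10.8-fold), heat shock genes fell in 14 of 17 and rose in 2 (camera adjusted p = 0.0444; FKBP4 4.62-fold), and matrix and adhesion genes fell in 17 of 25 and rose in 6 (camera adjusted p = 0.0327; ITGA4 7.34-fold, ITGA5 6.26-fold). Of 23 genes of cytarabine and anthracycline metabolism 14 fell and 6 rose (camera adjusted p = 0.0338), with the nucleoside transporter gene SLC29A1 down 25.6-fold from 123 ± 14.1 to 4.80 ± 0.423 CPM and GSTP1 4.71-fold. The counts adjusted over the list alone were the same for all 14 lists that passed. None of the 14 passed with an estimated correlation, where the adjusted p ran from 0.259 for granule and histone genes to 0.855 for oxidative phosphorylation and heat shock genes. DESeq2 size factors in edgeR moved the median log2 fold change of all genes from 0.06 to 0.10, so changes of that size cannot be separated from the scaling. The error of the scaling may be larger. Both scalings assume that most genes do not change, whereas 13143 of 15403 passed here. The near balance of higher and lower genes under the drug is therefore partly set by the scaling.

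**Figure D3:**
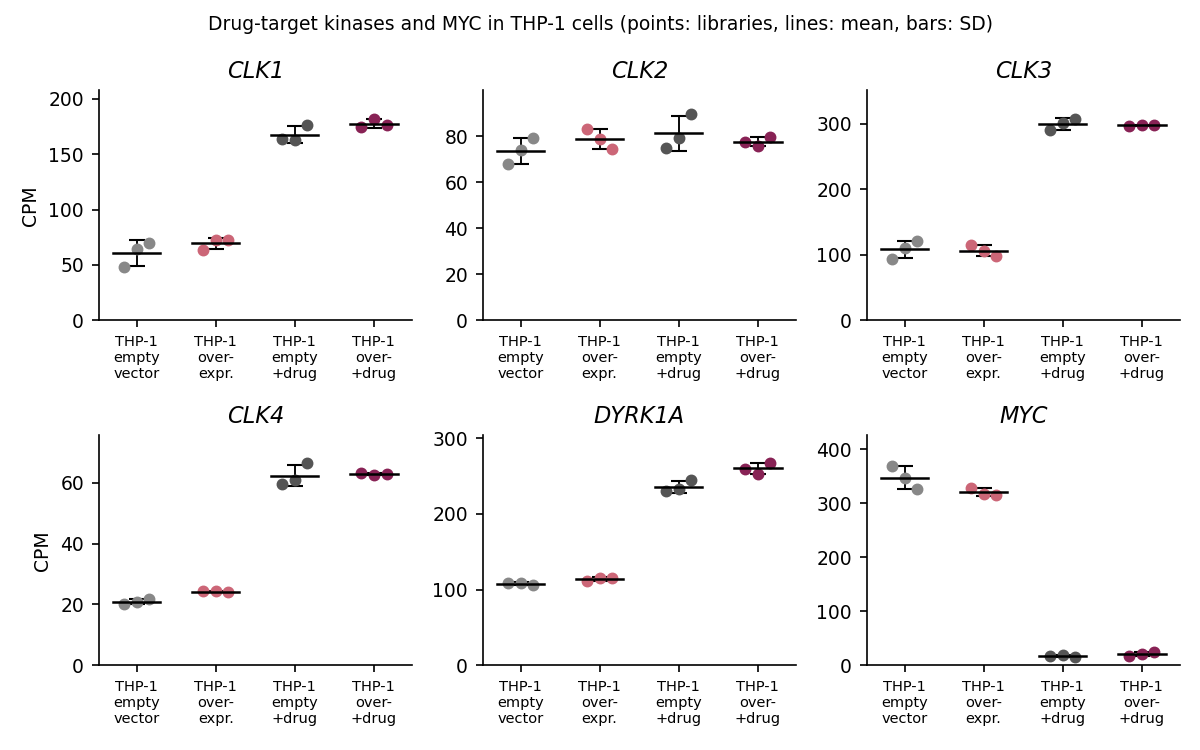
CPM of CLK1, CLK2, CLK3, CLK4, DYRK1A and MYC in the 4 THP-1 groups, with 1 point per library, a line at the mean and bars of 1 SD, on linear axes from 0. MYC fell from 348 to 16.8 CPM in empty vector cells and from 321 to 21.5 CPM in overexpressing cells, and CLK2 stood between 73.7 and 81.3 CPM in every group.

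In overexpressing cells the drug gave nearly the same picture, with 6692 genes higher and 6356 lower. MYC fell 14.9-fold, from 321 ± 7.05 to 21.5 CPM (log2 fold change -3.90, SE 0.11, adjusted p = 4.33e-13), and CLK3 rose 2.80-fold, CLK4 2.60-fold, CLK1 2.55-fold, DYRK1A 2.28-fold and CTNNB1 1.51-fold. CLK2 stood at 77.7 ± 1.89 against 78.7 ± 4.35 CPM (adjusted p = 0.819) and AXIN2 at 0.445 ± 0.104 against 0.479 ± 0.135 CPM (adjusted p = 0.834). Of 12037 genes changed by the drug with both vectors, 11879 moved in the same direction and 158 in opposite directions (r = 0.942 across genes, no shared libraries). ITGA8, an integrin gene without a count in untreated overexpressing cells, reached 28.1 ± 1.57 CPM (at least 1842-fold higher), and PRLHR, ZNF501, MYZAP, SLC17A8, LDHAL6B, ZFP91-CNTF, FOXI1, FBLN5 and TFCP2L1 rose from 0 counts by at least 724-fold to 1040-fold. RGS18 fell 58.7-fold, TIFAB 89.7-fold, SPATA12 63.4-fold, FYB1 43.4-fold, NEGR1 42.2-fold, NREP 41.8-fold, the BMP antagonist gene NOG 39.4-fold and CXCL10 38.4-fold, the last from 29.6 ± 1.07 to 0.771 ± 0.0780 CPM. The readthrough loci RAB4B-EGLN2 and MSH5-SAPCD1 fell 125-fold and 43.8-fold. Without overexpression with drug 3 the log2 fold change moved from -6.96 to -8.04 for RAB4B-EGLN2 (-6.14 without overexpression 3), from -6.49 to -11.31 for TIFAB and from -5.40 to -6.08 for NEGR1.

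The lists that passed in overexpressing cells were a subset of those in empty vector cells. Ribosomal protein genes rose in 75 of 77 cases (camera adjusted p = 1.69e-09; RPS19 2.17-fold), histone genes in 12 of 14 (camera adjusted p = 6.79e-07; H2BC12 31.1-fold), lysosomal genes in 20 of 30 with 5 lower (camera adjusted p = 0.00901; NEU1 5.22-fold) and the CLK, DYRK and HIPK kinases in 8 of 12 with 2 lower (camera adjusted p = 0.0461, and 0.0769 with library totals; HIPK3 2.35-fold). DNA replication genes fell in 31 of 37 with 2 higher (camera adjusted p = 3.22e-09; CDC45 9.75-fold), ATF4 genes in 23 of 31 with 5 higher (camera adjusted p = 2.32e-07; PCK2 15.4-fold, PSAT1 13.4-fold), ribosome biogenesis genes in 32 of 38 with 2 higher (camera adjusted p = 6.41e-05; POLR1E 4.32-fold), glycolysis and hypoxia genes in 18 of 30 with 9 higher (camera adjusted p = 0.00228; PDK1 9.20-fold) and granule genes in 9 of 11 with 1 higher (camera adjusted p = 0.00510; PRTN3 9.20-fold). Adjusted over the list alone the counts were the same, except for 10 higher glycolysis genes. None of these 9 lists passed with an estimated correlation (adjusted p 0.231 to 0.784), and the Wnt target list again did not pass camera (5 of 18 higher and 8 lower, camera adjusted p = 0.427).

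Whether the drug moved the overexpression genes back was asked next. Of 4306 genes changed by overexpression, S100A9 aside, the drug moved 1967 in the opposite direction in overexpressing cells (45.7%) and 1794 further in the same direction (41.7%), where independent lists would give 1821 and 1827. In empty vector cells the drug moved 1440 opposite to overexpression and 2353 in its direction, where independent lists would give 1833 and 1842. Set against untreated empty vector cells, 429 of the 1967 opposite genes did not pass the test, 1465 had passed the empty vector level to the other side and 73 still lay on the overexpression side. The 10 opposite genes with the largest changes lay near the floor without drug. MYZAP, RPH3A, IL19, SPATA21 and GPER1 had no count in the 3 overexpression libraries and between 0.0557 and 0.104 CPM in empty vector cells. In overexpressing cells with drug MYZAP reached 13.9 ± 1.28, RPH3A 5.08 ± 0.621, SPATA21 0.976 ± 0.417 and GPER1 0.745 ± 0.224 CPM, and IL19 had a value between those of RPH3A and SPATA21. INMT-MINDY4 had 1 count in the overexpression libraries, a ratio of 71.3 to empty vector (95% counting interval 12.3 to 2866), and its log2 fold change moved from -5.55 to -4.49 without empty vector 1 and to -7.13 without overexpression 3, with a smaller move without overexpression 2. GIMAP1-GIMAP5 and ENSG00000268083 had counts in 1 empty vector library each, and ENSG00000285777 and ENSG00000288683 stayed below 1 CPM in both comparisons. Of the 6 fits that left out 1 library, GIMAP1-GIMAP5 and ENSG00000268083 kept the overexpression call in 2, MYZAP and ENSG00000288683 in 3 and SPATA21 in 4. The pair shares the overexpression libraries: the correlation across genes was -0.114 with a covariance of -0.18, against -0.445 and -0.06 in simulations without effects. With the empty vector libraries shared, they were 0.177 and 0.27, against 0.495 and 0.06. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from the shared libraries. Without overexpression 2 the counts were 1268 opposite and 1071 in the same direction, and without overexpression 3 they were 1335 and 1156.

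Overexpression under the drug was compared next. Of 15403 genes 569 were higher and 740 lower, and 47 passed with a change of at least 2-fold. A fit of the 2 compared groups alone gave 973 higher and 863 lower genes. S100A9 was 7.67-fold higher (log2 fold change 2.94, SE 0.20, adjusted p = 1.8e-05), and S100A8 did not pass (log2 fold change 0.43, SE 0.25, adjusted p = 0.317). AKR1C2, an aldo-keto reductase, was 2.43-fold higher (27.2 ± 3.66 against 11.2 ± 1.81 CPM, n = 3 each, adjusted p = 0.00164), IGLL1 2.27-fold, the cytokine gene IL1B 1.85-fold, CHI3L1 1.81-fold, SUCNR1 1.76-fold and carbonic anhydrase gene CA2 1.71-fold. CLEC5A was 1.80-fold lower, HELLS 1.78-fold, FAM161B 1.72-fold, EPHB6 1.65-fold, EIF4E3 1.63-fold and MTAP 1.62-fold. ITSN1 (2.81-fold higher), PTGER3 (1.92-fold), OR5B2 (1.71-fold), PTGS1 (1.69-fold lower), CDK18 (1.63-fold) and the readthrough locus ARL2-SNX15 (21.2-fold) lost their call in 4 or 5 of the 6 fits that left out 1 library, with an adjusted p of up to 0.129, and ITSN1 moved from a log2 fold change of 1.49 to 2.51 without empty vector with drug 2.

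Of 30 mitotic genes 22 were higher and none lower (26 adjusted over the list alone; camera adjusted p = 1.38e-39; adjusted p = 0.0328 with an estimated correlation), with CCNB1 up from 207 ± 14.8 to 311 ± 6.71 CPM, DLGAP5 1.48-fold, CENPF 1.42-fold and TOP2A 1.30-fold. Ribosomal protein genes were higher in 61 of 77 cases (74 adjusted over the list alone; camera adjusted p = 7.78e-52), with RPS3A and RPS3 up 1.29-fold and 1.28-fold. DNA replication genes were lower in 17 of 37 cases (22 adjusted over the list alone; camera adjusted p = 6.11e-16), with MCM5 down 1.46-fold and CHAF1B 1.42-fold. Neither of these lists passed with an estimated correlation (adjusted p up to 0.297). Of 12 anti-apoptotic genes BIRC5, XIAP and CFLAR were 1.32-fold, 1.23-fold and 1.12-fold higher, also adjusted over the list alone (camera adjusted p = 0.00683). BIRC5 is also among the mitotic genes, and the list did not pass with an estimated correlation. MHC class II genes were higher in 3 of 11 cases (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0140), led by HLA-DRA at 2.10-fold, and mitochondrially encoded genes in 3 of 13 (7 adjusted over the list alone; camera adjusted p = 0.000136), led by MT-CYB at 1.31-fold (adjusted p = 0.496 and 0.543 with an estimated correlation). Cholesterol synthesis genes were lower in 6 of 23 (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 8.46e-05; DHCR7 1.36-fold) and NRF2 genes lower in 5 of 19 and higher in 1, also adjusted over the list alone (camera adjusted p = 0.000261; TKT 1.41-fold). With an estimated correlation their adjusted p was 0.596 and 0.293. The number of changed genes was 691 without empty vector with drug 1, 502 without 2, and 669, 543 and 775 without overexpression with drug 1, 2 and 3, and library totals gave 393 higher and 1555 lower genes. CFLAR and HLA-DRB5 (1.36-fold higher) passed in none of the 6 fits that left out 1 library (adjusted p at least 0.0714 and 0.0512), and HLA-DRA and MT-CYB passed in 2.

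The interaction asked whether the drug acted differently in overexpressing cells. Its effect differed for 2968 genes, 1239 with a more positive and 1729 with a more negative change in overexpressing cells. ATF4 genes fell further there: 22 of 31 had a more negative drug effect (24 adjusted over the list alone; camera adjusted p = 1.1e-28; adjusted p = 0.0345 with an estimated correlation). ASNS fell from 112 ± 3.08 CPM in overexpressing cells (log2 fold change -1.72, against -0.36 from 46.5 ± 4.03 CPM in empty vector cells) and GARS1 by -1.85 against -1.16, while DDIT3 rose by 1.59 against 2.41. With drug ASNS stood at 36.2 ± 1.62 CPM in empty vector and 34.0 ± 1.45 CPM in overexpressing cells, and DDIT3 at 42.1 and 45.3 CPM. For these genes the interaction came mostly from the untreated levels. GARS1 stood at 234 and 196 CPM with drug. The heat shock, cholesterol and folding lists, lower in untreated overexpressing cells, had more positive drug effects there: 12 of 17 heat shock genes (13 adjusted over the list alone; camera adjusted p = 4.27e-16), 14 of 23 cholesterol genes with 1 more negative (18 and 2; camera adjusted p = 3.1e-11) and 8 of 20 unfolded protein response genes (8; camera adjusted p = 0.000453). The adjusted p was 0.351, 0.456 and 0.692 with an estimated correlation. The interaction contains the untreated vector difference with its sign reversed. Lists low in untreated overexpressing cells are therefore pushed toward positive values, and no simulation without effects was run for this pair. HSPA1A changed by 1.71 on the log2 scale in overexpressing and by 0.15 in empty vector cells, INSIG1 by -1.05 against -2.03, HMGCS1 by 0.32 against -0.87 and PDIA4 by -0.54 against -1.36. With drug HSPA1A stood at 43.0 CPM in empty vector and 44.3 CPM in overexpressing cells, INSIG1 at 130 and 125, HMGCS1 at 99.3 and 111 and PDIA4 at 137 and 141. Mitotic genes had more positive effects in 24 of 30 cases (27, and 1 more negative; camera adjusted p = 5.05e-23), with CDC20 up by 1.18 against 0.29 and CCNB1 by 1.18 against 0.40 (adjusted p = 0.0874 with an estimated correlation).

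Oxidative phosphorylation genes had a more positive drug effect in 26 of 68 cases and a more negative one in 1 (30 and 2 adjusted over the list alone; camera adjusted p = 2.04e-08; UQCRH 0.69 against 0.23), mitochondrially encoded genes in 6 of 13 (10; camera adjusted p = 4.45e-07; MT-CYB 0.85 against -0.22), ribosome biogenesis genes in 8 of 38 (8; camera adjusted p = 5.06e-06; NOLC1 -1.22 against -1.68), ribosomal protein genes in 4 of 77 (0; camera adjusted p = 0.000399; RPS15 0.83 against 0.57), immediate early genes in 6 of 32 (6; camera adjusted p = 0.0190; SPRY4 0.50 against -1.11) and lysosomal genes in 7 of 30 with 2 more negative (8 and 3; camera adjusted p = 0.0461, and 0.109 with library totals; CTSA 0.16 against -0.55). The drug effect was more negative for 11 of 30 glycolysis and hypoxia genes and more positive for 3 (11 and 4; camera adjusted p = 0.0140; PDK1 -3.20 against -2.02) and more negative for 12 of 37 DNA replication genes and more positive for 1 (13 and 1; camera adjusted p = 0.00334; CDT1 -0.55 against 0.19). Counts in parentheses are adjusted over the list alone. With drug, empty vector and overexpressing cells stood at 4.29 and 4.37 CPM for SPRY4, 105 and 99.7 for CTSA and 136 and 143 for NOLC1. Without drug these genes stood at 9.23 and 3.09, 153 and 89.0, and 437 and 332 CPM, so their interaction came mostly from the untreated levels. The levels with drug lay further apart for PDK1 (177 and 116), MT-CYB (2569 and 3364), CDT1 (78.6 and 60.2), UQCRH (295 and 354) and RPS15 (740 and 913). With an estimated correlation the 8 lists of this paragraph had an adjusted p between 0.456 and 0.732. MYC fell less in overexpressing cells (difference 0.47, SE 0.14, adjusted p = 0.0304), S100A8 rose more (1.42, SE 0.39, adjusted p = 0.0221), and the call was kept in 4 and 9 of the 12 fits that left out 1 library. The number of genes was 1885 without overexpression 2, and library totals gave 961 more positive and 2379 more negative effects.

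**Figure D4:**
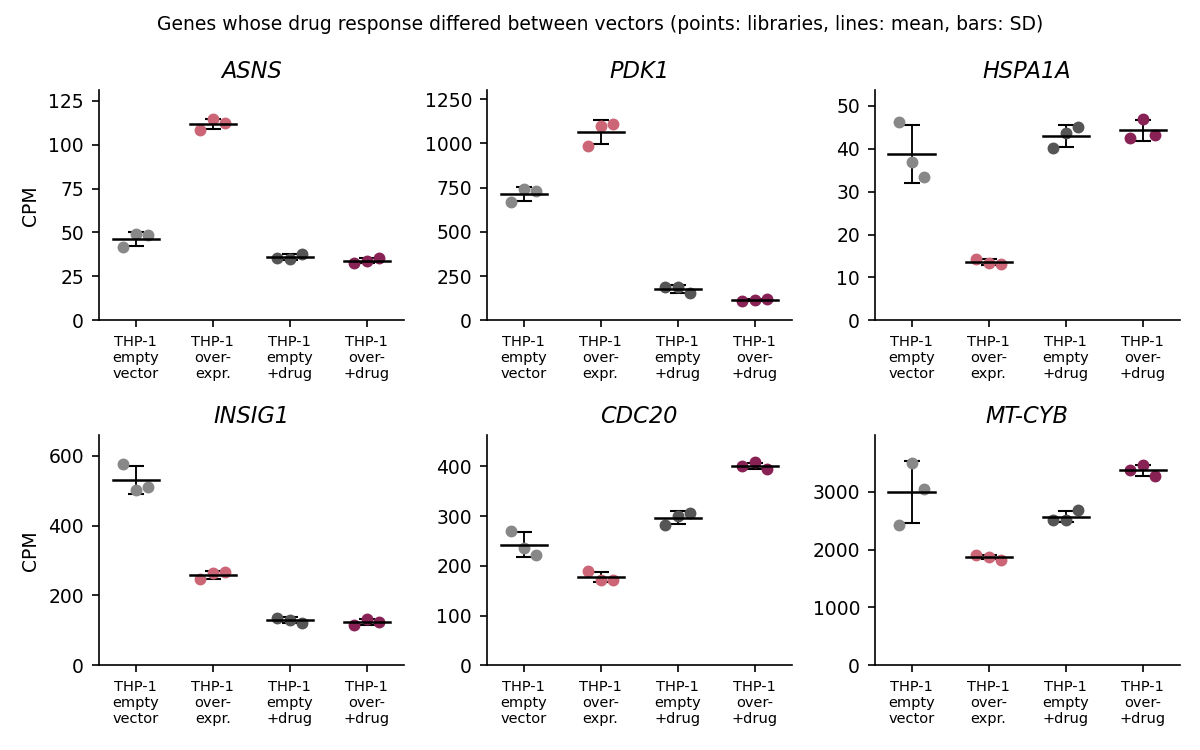
CPM of ASNS, PDK1, HSPA1A, INSIG1, CDC20 and MT-CYB in the 4 THP-1 groups, with 1 point per library, a line at the mean and bars of 1 SD, on linear axes from 0. ASNS stood at 46.5 and 112 CPM in untreated empty vector and overexpressing cells, and INSIG1 at 529 and 259 CPM. With drug ASNS stood at 36.2 and 34.0 CPM and INSIG1 at 130 and 125 CPM.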

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

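Among the tests below, those of counting noise, of the permuted labels with the vector effect removed, of a state that varies between libraries of 1 group and of the spread among THP-1 empty vector libraries were chosen only after the result was seen.

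The drug effect differed between the vectors for 2968 genes. The overexpression minus empty vector difference of the log2 drug effects was 1.42 for S100A8. It was most positive for MYZAP (5.65), RPH3A (5.10), C13orf42 (4.43), GDA (4.06) and ABHD14A-ACY1 (3.53), and most negative for ARL2-SNX15 (-9.08), KBTBD11-OT1 (-8.11), ATP6V1G2-DDX39B (-3.47), GET1-SH3BGR (-3.43) and CHRNE (-3.19). Without drug MYZAP, RPH3A, C13orf42 and GDA had 0 counts in overexpressing and 6 to 16 in empty vector cells, and CHRNE had 3, ARL2-SNX15 9, KBTBD11-OT1 12 and GET1-SH3BGR 17 in empty vector cells, so these log2 values depend on the floor. Leaving out 1 library moved CHRNE to -6.30 and MYZAP to 4.25, GDA to 3.12 and ABHD14A-ACY1 to 1.86 (empty vector 3), KBTBD11-OT1 to -13.09 and GET1-SH3BGR to -5.84 (empty vector 2), CHRNE to -2.59 and C13orf42 to 3.57 (empty vector 1), and ARL2-SNX15 to -4.99 (overexpression 1). GDA passed in 1, GET1-SH3BGR and KBTBD11-OT1 in 2 and ABHD14A-ACY1 in 4 of the 12 fits that left out 1 library, with an adjusted p of up to 0.119. For the first gene of each list that passed, it was 0.66 for DLGAP5, -0.74 for CDT1, 0.46 for NOLC1, 0.26 for RPS15, 0.46 for UQCRH, 1.07 for MT-CYB, -1.19 for PDK1, 0.97 for INSIG1, -1.36 for ASNS, 0.81 for PDIA4, 1.56 for HSPA1A, 1.60 for SPRY4 and 0.72 for CTSA. The mean over the members was 0.39 for mitotic genes, -0.16 for DNA replication, 0.26 for ribosome biogenesis, 0.0942 for ribosomal proteins, 0.19 for oxidative phosphorylation, 0.38 for mitochondrially encoded genes, -0.20 for glycolysis and hypoxia, 0.45 for cholesterol synthesis, -0.70 for ATF4 genes, 0.36 for the unfolded protein response, 0.72 for heat shock, 0.18 for immediate early genes and 0.01002 for lysosomal genes.

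For the interaction, 50 draws of permuted vector labels gave at most 861 genes besides the real 2968, but a vector effect without an interaction also keeps such counts low. With the additive vector effect of each gene removed from the counts, 1 of the 50 draws, the real one, gave as many genes. The highest of the others was 874 (33 before the removal) against 3043. This argues against a chance assignment of these libraries to the vectors. It cannot exclude a difference between cultures, since no label says that replicates were separate cultures. After the removal 335 genes still passed between the untreated vectors, since only the mean of the vector effects over both drug levels was taken out. The other comparisons have 10 splits of 6 libraries, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real value and the highest other were 231 and 2 for the knockdown, 4307 and 4 for overexpression, 13143 and 0 for the drug in empty vector cells, 13048 and 0 for the drug in overexpressing cells, and 1309 and 3 for overexpression under the drug.

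The THP-1 overexpression difference lay on an axis along which libraries within both U937 groups and within THP-1 empty vector also spread. The deviation of U937 empty vector 2 from its group correlated with it with r = 0.534 across 9978 genes and that of U937 shS100A9 3 with r = 0.578, as a state that varies between libraries of 1 group would give. Within THP-1, empty vector 3 minus 1 correlated with overexpression minus empty vector 2 with r = 0.404, and the other arrangements gave 0.305 and 0.190, while the 3 arrangements within the overexpression libraries gave -0.192, 0.0494 and 0.228. A depth difference was argued against: with every THP-1 library thinned to 38.4 M counts 4086 genes passed, 3916 of them among the 4307 and with the same direction. Over genes called in the overexpression, the knockdown changes correlated with the overexpression changes with r = 0.344, which goes against the amount of S100A9. Over the 223 genes called in the knockdown r was -0.0613, which does not go against it. The knockdown was also made in another line, so the amount of S100A9 stays open. The same deviations of U937 empty vector 2 and shS100A9 3 had an r of 0.00794 and -0.0447 with the overexpression difference under the drug. With the drug effect in empty vector cells, which shares the untreated empty vector libraries, r was 0.252 and 0.245. Part of the overexpression difference without drug may be the state that varies between libraries.

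In U937 cells 15 genes were almost lost in the knockdown: AFDN, SNRPN, CD109, RAPGEF6, SPINT1, GPR85, SPRED1, HVCN1, XAF1, METTL7B, SIGLEC9, CYB5A, C2orf72, HDHD3 and GTF2IRD1 kept a median of 1.64% of the empty vector level, and 1 gene, IFI44, showed the reverse. Loss of chromosome segments that span neighbours was argued against for the genes as a set. Their 25 nearest expressed neighbours, from which the 15 genes themselves were left out, had a median ratio of 0.883. A pooled median cannot exclude a loss at a single locus. Such a loss stays open for RAPGEF6 and GPR85, whose neighbours CDC42SE2 and SMIM30 had ratios of 0.147 and 0.449. Their neighbours on the other side, SLC22A4 and BMT2, had ratios of 0.511 and 1.17. Loss of a segment also stays open for CD109, whose only neighbour found had a ratio of 0.544. The only neighbours found for AFDN and SNRPN lay 732 and 355 kb away and say little about those loci. The test of counting noise cannot decide. The genes were chosen by an adjusted p below 0.05, at least 2 CPM in empty vector and less than 0.1 of that level left. Such losses from counting alone were thus almost impossible beforehand, with an expected number of 4.63e-67 over the 13016 genes tested. Counting error is also smaller than the spread between these libraries. The amount of S100A9 stays open: 1 of the 15, XAF1, was higher in the THP-1 overexpression and 1, METTL7B, lower, and that is another line. Whether the vectors went into different cells of a mixed U937 stock was not tested.

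Under the drug 181 genes silent in empty vector cells were on, and 2029 stayed off. Of the former 58 (32.0%), SLC5A5, SLC17A8 and FBLN5 among them, lay within 20 kb downstream of an expressed gene on the same strand, against 125 (6.16%) of the latter, a ratio of 5.20 (Fisher's exact test, two-sided, p = 1.09e-22). Gene-dense surroundings were argued against, since the ratio for expressed genes on the other strand was 1.36, or 0.262 of that for the same strand. Reads running on past the end of expressed genes under the drug may account for part of these genes, as a hypothesis. The strand setting of the counting is not given in the sources used here.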

How the results depend on the processing

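The alternatives without the U937 libraries that stood apart, and with a term for them, were chosen only after the result was seen. The cause of the changes below was not tested, apart from the 2-fold threshold, which is stricter by construction, and fits that left out a library, which had fewer samples.

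Counts of changed genes, in the order knockdown, overexpression, drug in empty vector cells, drug in overexpressing cells, overexpression under the drug and interaction, were 134, 283, 7309, 7420, 47 and 303 with a threshold of 2-fold. DESeq2 gave 790 for the knockdown and 1998 for overexpression under the drug. The replicate number as a block gave 3 for the knockdown; replicates with the same number were not more alike than others (r -0.345 to 0.0922 in U937, -0.112 to 0.0703 in THP-1). For the knockdown, 4296 genes passed without the libraries that stood apart and 2201 with a term for them, and both included the 231 genes in the same direction. With 1 library left out the counts ran from 18 to 362 for the knockdown (18, 362 and 20 without empty vector 1, 2 and 3, and 21 without shS100A9 1 or 2), 2735 (without overexpression 2) to 4983 for overexpression, 502 to 1174 for overexpression under the drug (691 and 502 without empty vector with drug 1 and 2, and 669, 543 and 775 without overexpression with drug 1, 2 and 3) and 1885 (without overexpression 2) to 3724 for the interaction. Library totals gave 1948 genes for overexpression under the drug and 3340 for the interaction, with more of them lower. The 2 compared groups alone gave 1836 genes for overexpression under the drug, with more of them higher.

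Genes changed in opposite and in the same direction by knockdown and overexpression numbered 69 and 181 with DESeq2, 0 and 0 with the block (edgeR), 308 and 1365 without the libraries that stood apart, 148 and 743 with a term for them, and 1 and 3 with the 2-fold threshold. With 1 library left out they ran from 3 to 24 and from 2 to 121, each of these in U937. For the drug against overexpression they were 115 and 94 with the 2-fold threshold, and ran from 1268 to 2220 and from 1071 to 2112 with 1 library left out (the lowest without overexpression 2).

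The number of gene lists that passed went from 6 to 0 (knockdown), 15 to 1 (overexpression), 14 to 0 and 9 to 0 (drug), 8 to 1 (overexpression under the drug) and 13 to 1 (interaction) with an estimated correlation. Fry gave 0 for the knockdown and 33 for each drug comparison, and camera with the block 12 for the knockdown. Of 2808 values of named genes with 1 library left out, 2514 kept their call, 291 lost and 3 gained it, and none reversed; under the other settings it was 2711, 63 and 5 of 2779. Depth limits genes at the floor, where a log2 fold change depends on the smallest count.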

Other observations

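Overexpression changed 510 genes both without and with the drug, 294 in the same and 216 in opposite directions, where independent lists would give 181 and 184 (Fisher's exact test of the directions, two-sided, p = 0.000249). S100A9 aside, the correlation across genes was -0.0137.

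The following hypothesis was tested: reduced splicing under the drug lowers genes with many introns. The test of transcript length itself was chosen only after the result was seen. The drug effect and introns per kb had a rho of -0.114 in empty vector and -0.150 in overexpressing cells. Gene length was argued against only by the criteria chosen later: transcript length and the drug effect had a rho of 0.0107 and -0.0148, and inside 5 bins of length the rho for introns per kb was below 0 in each bin with either vector. The median over the bins was -0.105 and -0.159. These medians lay outside both ranges set beforehand, so the planned test could not tell. Splicing output stays open: neither rho reached the bound set beforehand for it, and other properties of genes with many introns were not tested. A negative relation was also seen for overexpression under the drug, where both groups had the drug. There rho was -0.179, with a median of -0.212 inside the bins of length. In the comparisons without drug rho was positive, at 0.0546 for overexpression and 0.0605 for the knockdown. The negative relation was thus seen only where libraries with drug were compared. Of 488 intronless genes 298 rose (61.1%), against 43.6% of genes with introns. Genomic DNA was argued against as a source of the rise of these 298 genes, whose median rise was 1.67 CPM per kb. The 1893 genes without a count in untreated empty vector cells had a median of 0.00996 CPM per kb under the drug, 0.00596 of that rise.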
